A study of Homo sapiens with 2 samples.

How the data were processed

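Gene expression was measured in HepG2, a human hepatoma (liver cancer) cell line, on 2 Affymetrix microarrays. 1 array held RNA of control cells and 1 held RNA of cells treated for 24 h with 100 mg/L of silica nanoparticles in amorphous form (SiO2-NP). Per the labels' protocols, cells grew in MEM medium, total RNA was extracted with a column kit, and about 300 ng of each RNA was amplified with a whole-transcript kit and labelled with biotin. The labels give no replicate cultures, no particle size and no serum content of the medium.

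The deposited table holds 1 log2 intensity per transcript cluster (a set of probes read out together, called a probe here) and array. The scale was read from the values, which run from 2.08 to 14.4, with medians of 6.65 in the control array and 6.69 in the SiO2-NP array. Per the submitters' processing notes, the tools RMA and MAS5 were used; which of them made the deposited values, and their versions and settings, are not given in the sources used here. RMA sets the probe distributions of the arrays equal before it summarises them, so a change shared by most transcripts would not be seen in such values. The scanner files and their background and detection calls are not used here, so a dim probe could not be told from an absent transcript. An array has no read depth, and the number of arrays limits the precision.

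Genes were named through the platform annotation supplied with the table. Of the 33297 probes, 19460 had 1 gene symbol, 1754 had several and were left out, and 12083 had none in that annotation. Of the single-symbol probes, 19429 had a gene identifier found in the RefSeq gene table of GRCh38.p14, which was used for current symbols and left every symbol as it was. Probes of 1 gene were averaged (769 genes had several), which gave 18417 genes. No coordinates are given, because the sources do not state the build behind the probes. Genes were called expressed when their mean over both arrays reached the median gene mean, a log2 intensity of 7.26, which left 9209 genes. This is a level filter and not a detection call.

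The effect is the log2 difference, SiO2-NP minus control. With 1 array per group there is no replicate error, so no test was run, no p-value or SE is given, and every difference describes these 2 arrays and not the conditions. The words higher and lower are used in that sense. Expressed genes were counted at a difference of 1.5-fold (0.58 on the log2 scale) or more. A set of 37 gene lists was fixed, of which 34 had at least 5 expressed members. Each list's median difference was placed among 10000 random lists of the same size, drawn from the expressed genes and matched on mean expression in 20 bins. A list outside the central 95% of them (below the 2.5th or above the 97.5th percentile) was said to stand apart. Chance alone would place on average 1.7 of 34 lists outside. Gene lists share co-regulated members, so a list can stand apart more easily than independent genes would.

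The genes named were chosen by a rule: the 12 expressed genes with the largest positive and the 12 with the largest negative difference, leaving out small RNAs, olfactory receptors, clone names and uncharacterised loci; the 4 members with the largest absolute difference of each list that stood apart; up to 2 of each other list; and ALB, HMOX1, MT2A, DDIT3, HSPA5, CDKN1A, CXCL8, HMGCS1, ACTB and GAPDH. Small RNAs were summarised as a class. The lists, the rule, the thresholds and the alternative settings (no filter or a stricter filter on dim genes, a 2-fold threshold, centring on the median or on a running median of 501 genes by level, quantile normalization, other rules for several probes or symbols, all measured list members, unmatched random lists, the list mean, and lists without their most extreme member) were written before the data were examined. Alternative pseudocounts, planned for linear values, were not needed on a log2 table.

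The steps were tested on simulated data: differences taken from the real arrays were shuffled between genes of like level, and 200 genes were given known folds. Over 9209 expressed genes, 98.0% of genes set to 2-fold and 56.0% of those set to 1.5-fold passed the 1.5-fold threshold, and 0.433% of the unchanged genes did. Of 100 simulated lists without a shift, 6 stood apart, and 39 of 40 lists shifted by 0.2 on the log2 scale did. The simulated noise holds the real differences too, so it does not give an error rate for the real genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.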

Results

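The data comprised 2 arrays of 33297 probes each, 1 of control HepG2 cells and 1 of HepG2 cells exposed to 100 mg/L amorphous SiO2-NP for 24 h, and the design implied 1 comparison: which transcripts differed in the exposed hepatoma cells. The log2 intensities of the 2 arrays correlated across all probes with a Pearson r of 0.994, and across the 9209 expressed genes with 0.991 (genes are not independent replicates). The expressed genes had a median difference of -0.03 and an SD of 0.16 across genes, and the central 95% of them lay between -0.37 and 0.28 on the log2 scale. No value below has a replicate error, because each group held 1 array.

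Few transcripts differed by much between the exposed and the control cells, and 8 of the 13 that were at least 1.5-fold higher were lipid synthesis list members. Of the expressed genes, 13 were at least 1.5-fold higher and 23 at least 1.5-fold lower after SiO2-NP, together 0.391% of those considered. At 2-fold the counts were 1 and 4. Of the 13 higher genes, 6 belonged to the list for cholesterol biosynthesis and 2 to the list for fatty acid synthesis. The 23 lower genes included 6 small nucleolar RNAs, the 3 vault RNAs of the VTRNA1 family and 2 zinc finger genes. The split of 13 higher to 23 lower depended on the scaling: it was 21 to 19 after centring on a running median by level, where 10 of the 21 were members of the lipid lists, 22 to 18 after quantile normalization, and 12 to 28 after centring on the median. The counts also depended on the level filter, with 61 higher and 68 lower without it and 9 and 8 with a filter at the 75th percentile.

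**Figure D1:**
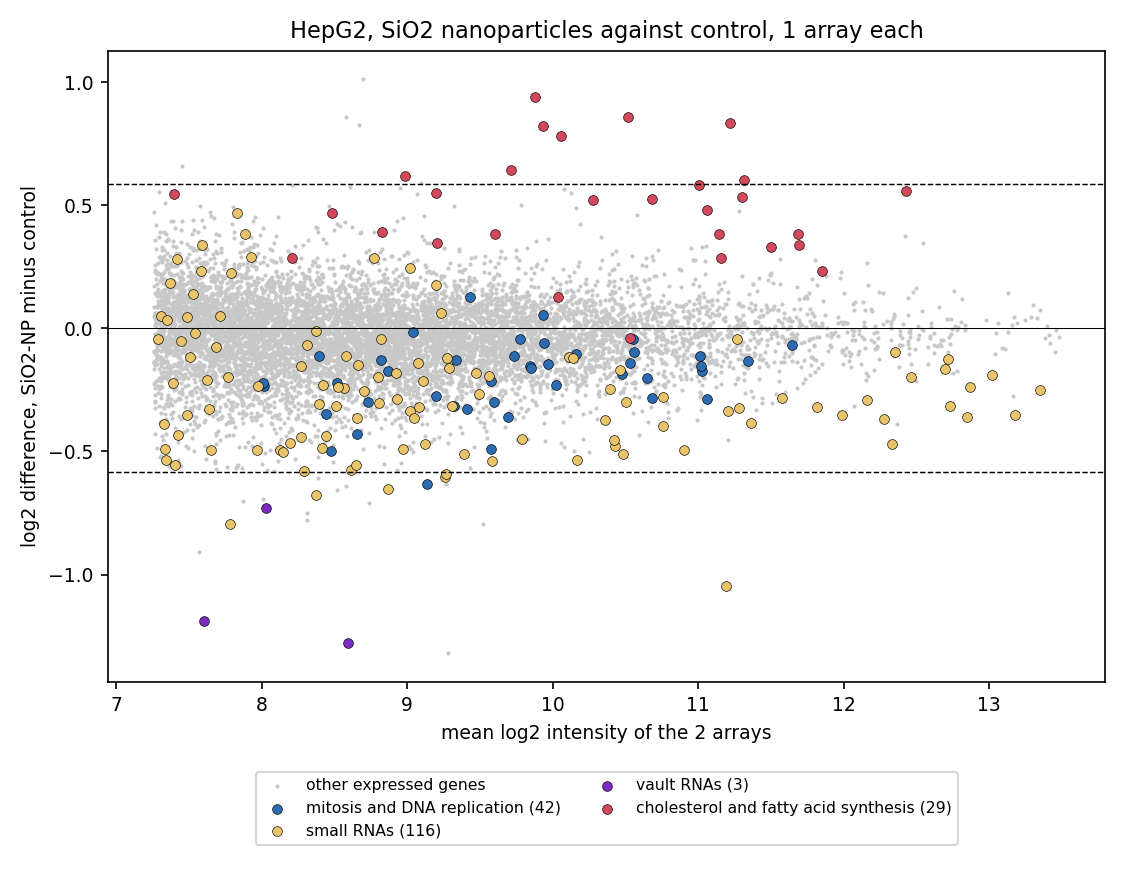
Log2 difference (SiO2-NP minus control) of each of the 9209 expressed genes against its mean log2 intensity over the 2 arrays; dashed lines mark 1.5-fold, and coloured points are the gene groups in the key with their numbers of expressed genes. Most of the 29 cholesterol and fatty acid synthesis genes lie above the other genes of like intensity, and most of the 42 mitosis and DNA replication genes and the 116 small RNAs lie below 0.

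Cholesterol synthesis genes were higher in the exposed cells as a group. All 15 expressed members of the list were above the control, with a median log2 difference of 0.55, or 1.46-fold, and 6 reached 1.5-fold. DHCR7, which catalyses the last step of cholesterol synthesis by the Kandutsch-Russell route, was 1.78-fold higher (log2 intensity 10.80 in the control and 11.64 after SiO2-NP). The mevalonate pathway genes MVD, FDPS and HMGCS1 were 1.77-fold, 1.56-fold and 1.52-fold higher. LSS, the cyclase that makes lanosterol, was 1.72-fold higher, and STARD4, a sterol carrier, was 1.53-fold higher. The list median lay at percentile 100 of the random lists, whose central 95% ran from -0.11 to 0.03.

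Fatty acid synthesis genes were higher as well, in 13 of 14 expressed members, with a median difference of 0.43 (1.34-fold) and 2 members past 1.5-fold. ACSS2, which makes acetyl-CoA from acetate, was 1.92-fold higher (9.41 against 10.35), and the fatty acid desaturase FADS2 was 1.81-fold higher. The desaturase SCD, already abundant at 12.15 in the control, was 1.47-fold higher, and the elongase ELOVL6 was 1.46-fold higher. This list also lay at percentile 100 of its random lists, which ran from -0.11 to 0.04. The fatty acid oxidation list did not stand apart, with a median of -0.00 over 12 expressed genes at percentile 75.8. Its members with the largest differences were ETFDH (-0.36) and ACSL1 (0.29).

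**Figure D2:**
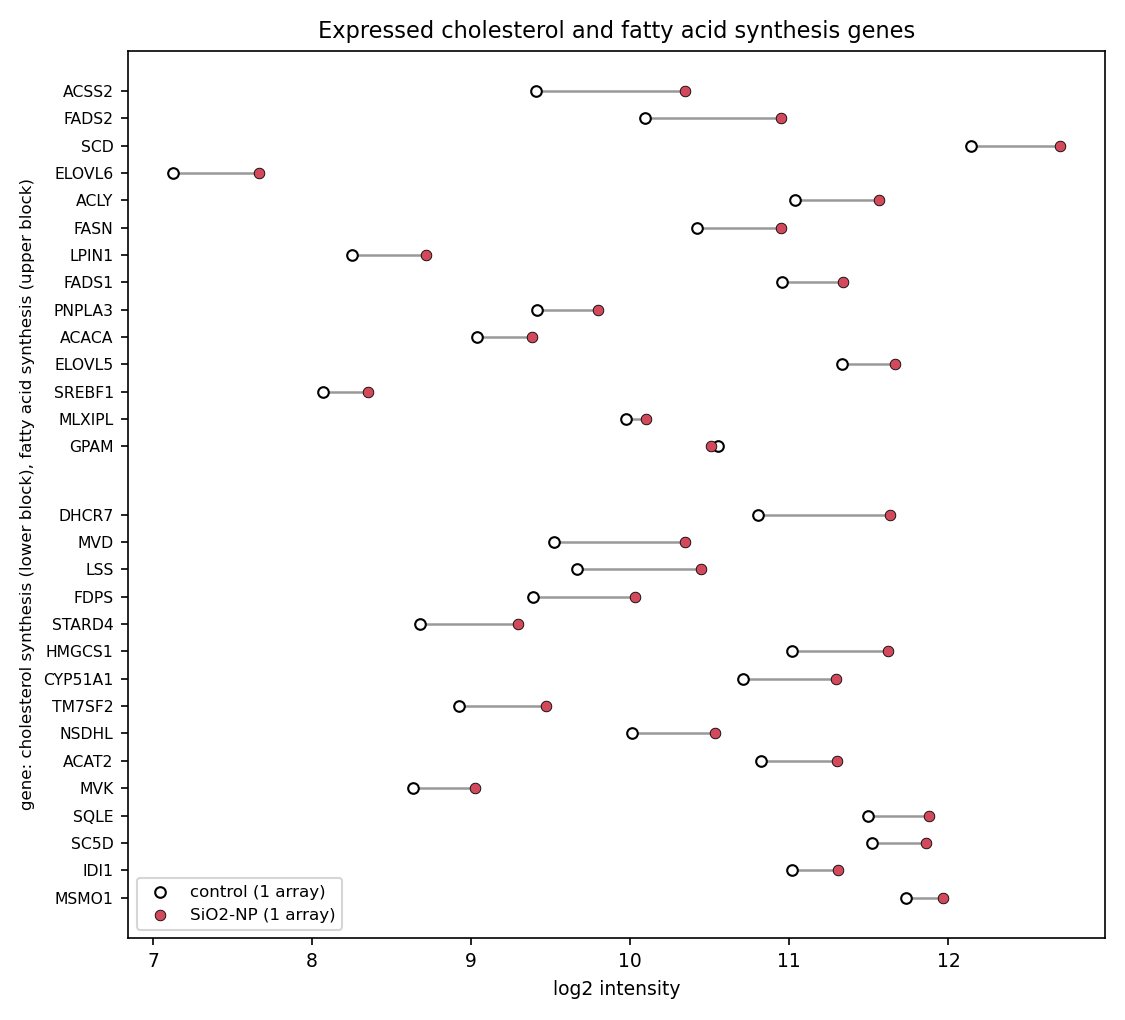
Log2 intensity of each expressed member of the cholesterol (15 genes) and fatty acid (14 genes) synthesis lists in the control array (open) and the SiO2-NP array (filled), sorted by difference within each list. In 28 of the 29 genes the SiO2-NP value is the higher one, and GPAM is the exception.

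Among the expressed genes with a symbol, the largest positive difference lay outside the lipid lists. ALDOC, an aldolase isoform of glycolysis, was 2.02-fold higher (8.19 in the control and 9.20 after SiO2-NP). TMC7, a member of the transmembrane channel-like family, was 1.81-fold higher, the transcriptional repressor BHLHE40 was 1.77-fold higher, and the membrane serine protease PRSS8 was 1.58-fold higher. The remaining gene of the 13 was the glucose transporter SLC2A3, with a difference of 0.59. The naming rule did not cover it, so it was named after its value was seen, and it shares sequence with its paralogue SLC2A14.

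Proliferation genes were lower as groups, by less than the lipid genes were higher. All 20 expressed DNA replication genes were below the control, with a median of -0.17, and 20 of 22 mitosis genes were, with a median of -0.17. The 2 mitosis genes above the control were AURKB (0.13) and MKI67 (0.05). Replication-dependent histones were lower in 12 of 13 expressed members, with a median of -0.19. Their list is named core histones but also holds linker histones such as H1-5. The 3 lists lay at percentiles 0.02, 0 and 0.1 of their random lists. CDK1, the mitotic kinase, was the only member of the 3 lists past 1.5-fold, 1.55-fold lower (9.45 against 8.82). The spindle checkpoint kinase TTK differed by -0.50, the kinetochore motor CENPE by -0.43 and DLGAP5 by -0.36. Among replication genes RRM2, a subunit of ribonucleotide reductase, differed by -0.49, the helicase subunits MCM6 and MCM7 by -0.35 and -0.28, and CDC45 by -0.30. The histones H1-5, H3C2, H2BC8 and H4C2 differed by -0.33, -0.30, -0.30 and -0.25, and histone genes share sequence, so their probes may read more than 1 of them. MND1, a meiotic recombination factor, and DEPDC1, 2 of the 12 lowest genes, were 1.62-fold and 1.58-fold lower. Zinc finger (ZNF) genes, a large family, also had a lower median on the same arrays, -0.09 over 207 expressed genes.

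The expressed gene with the largest negative difference was MTND2P28, a nuclear pseudogene that shares its sequence with mitochondrial ND2. It was 2.49-fold lower (9.94 against 8.62), and its probe may not separate the copies. The vault RNAs VTRNA1-2, VTRNA1-1 and VTRNA1-3, similar small non-coding RNAs of the vault particle, were 2.42-fold, 2.28-fold and 1.66-fold lower. Small RNAs as a class were lower in 99 of 116 expressed members, with a median of -0.28 against a range of -0.06 to -0.00 in random lists. Over all 396 measured small RNAs the median was -0.09. The expressed small nucleolar RNAs had medians of -0.30 (SNORA) and -0.32 (SNORD), while the 16 expressed MIR genes had 0.12. ADH4, an alcohol dehydrogenase, was 1.88-fold lower, GSTA1, a glutathione transferase, was 1.74-fold lower, and GPD1, glycerol-3-phosphate dehydrogenase, was 1.68-fold lower. NDUFB3, a subunit of respiratory complex I, was 1.62-fold lower, and ZNF845 and ZNF724 were 1.72-fold and 1.63-fold lower.

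A further 5 lists stood above their random lists, each with a small median. The NF-kB list had a median of 0.12, with all 7 expressed members above the control, among them RELB (0.30), the adhesion molecule ICAM1 (0.26) and the chemokines CXCL8 and CCL20 (0.12 each). Hepatocyte transcription factors had a median of 0.09, with 8 of 10 members above the control, led by ONECUT2 (0.19), NR5A2 (0.17), GATA6 (0.16) and GATA4 (0.15). The immediate-early and MAPK feedback list had a median of 0.08, with 12 of 15 above, of which EGR1 was 1.42-fold higher, and PHLDA1, FOS and JUNB differed by 0.20, 0.19 and 0.17. The list of YAP and SRF targets had a median of 0.08, with 11 of 14 above, among them CCN2 (0.27), THBS1 (0.19) and MYL9 (0.16), while AXL differed by -0.14. The hypoxia and glycolysis list had a median of 0.06, with 10 of 12 above, where ALDOC was followed by ALDOA (0.20), NDRG1 (0.17) and SLC2A1 (0.16). The NF-kB list lay at percentile 79.6 when its 8 dimmer measured members were included, and the hypoxia and glycolysis list at 97.1. Keratin-associated protein (KRTAP) genes, which encode hair proteins, had a median of 0.19 over 17 genes above the level filter in the same arrays.

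**Figure D3:**
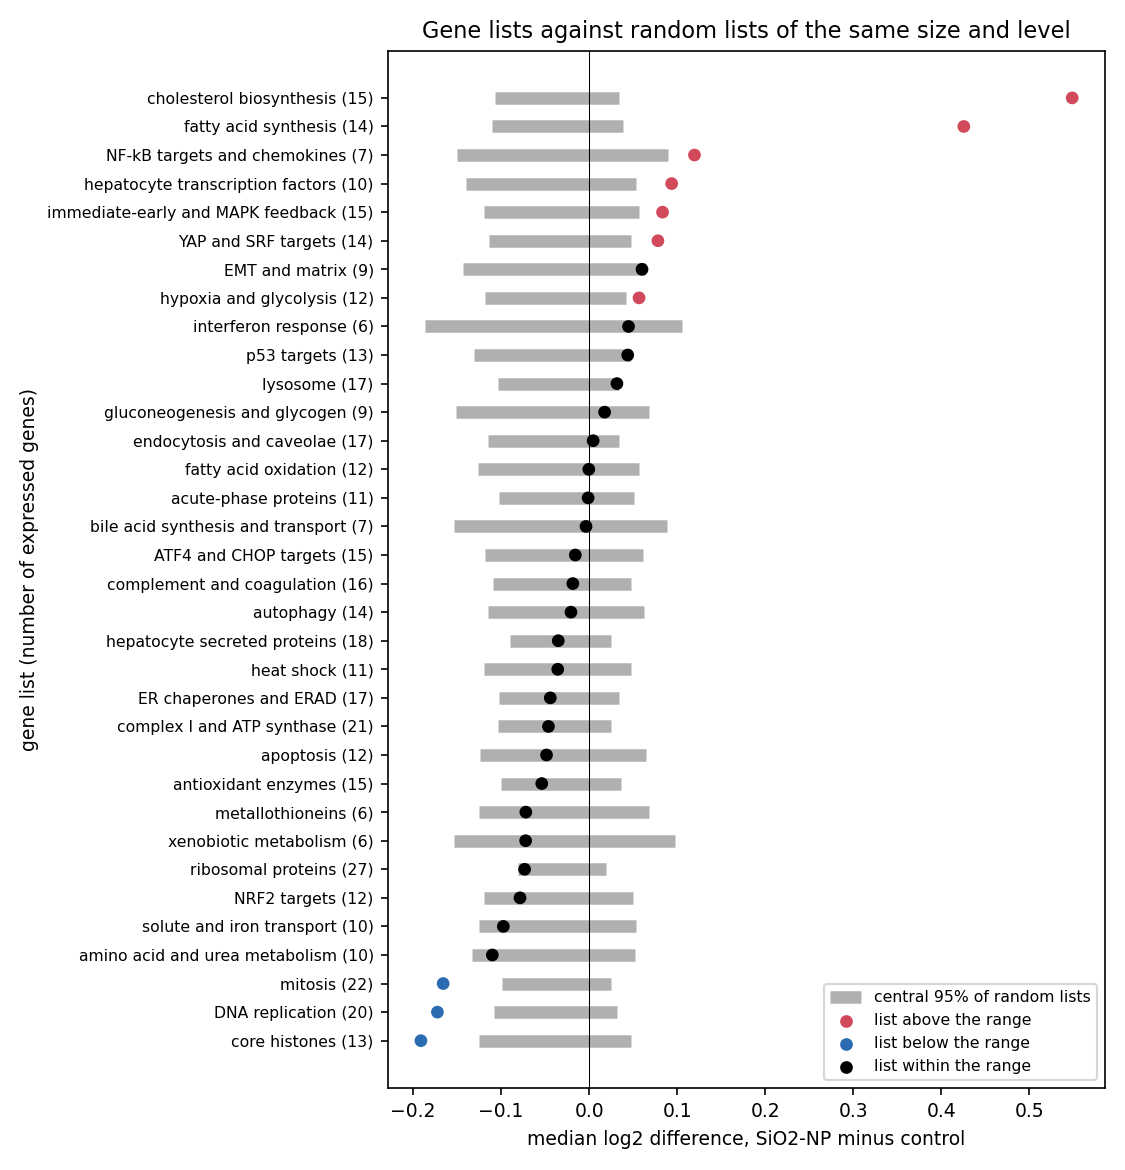
Median log2 difference (SiO2-NP minus control) of each of the 34 gene lists with at least 5 expressed members (points) and the central 95% of 10000 random lists of the same size and level (grey bars). The lists for cholesterol (0.55) and fatty acid (0.43) synthesis lie far to the right of their bars. The lists named core histones (which also holds linker histones), DNA replication and mitosis lie to the left of theirs.

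The lists for stress responses did not stand apart by their medians. By their means, the antioxidant enzymes lay at percentile 2.34 and the p53 targets at 99.0, both outside the range. The median difference was -0.07 over 6 expressed metallothioneins, -0.08 over 12 NRF2 targets, -0.05 over 15 antioxidant enzymes, -0.04 over 17 genes for ER chaperones and ER-associated degradation, -0.02 over 15 ATF4 and CHOP targets and -0.04 over 11 heat shock genes. It was 0.04 over 13 p53 targets, -0.05 over 12 apoptosis genes and 0.04 over 6 interferon response genes. HMOX1, the haem oxygenase induced by oxidative stress, differed by -0.15, the metallothionein MT2A by -0.03, the ER stress factor DDIT3 by 0.04, the ER chaperone HSPA5 by -0.04 and the cell cycle inhibitor CDKN1A by 0.06. The largest differences within these lists included AKR1B10 (-0.45), TXN (-0.36), MT1M (-0.34), MGST1 (-0.28), SEC61B (0.24), DNAJC3 (-0.22), TRIB3 (0.26), HSPB1 (0.32), TP53INP1 (0.45), BBC3 (0.32), CYCS (-0.22) and IRF7 (0.22). GSTA1, described above, belonged to the antioxidant list. With 1 array per group, no difference of any size, here or in the other lists, can be told from variation between cultures.

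Liver functions also lay within the range of random lists by their medians; by its mean, the list for amino acid and urea metabolism lay below it, at percentile 1.12. The median was -0.04 over 18 hepatocyte secreted proteins, -0.00 over 11 acute-phase proteins, -0.02 over 16 complement and coagulation genes, -0.11 over 10 genes of amino acid and urea metabolism and 0.02 over 9 genes of gluconeogenesis and glycogen. It was -0.00 over 7 bile acid genes, -0.07 over 6 genes of xenobiotic metabolism and -0.10 over 10 iron transport genes, the last of which was 0.0058 with all measured members. ALB, which encodes albumin, differed by -0.10. Larger differences were seen for BHMT (-0.46) and MAT1A (-0.40) of methionine metabolism, G6PC1 (-0.46) of glucose output, HAMP (-0.40), which encodes the iron hormone hepcidin, and CYP7A1 (-0.39), the rate-limiting enzyme of bile acid synthesis. SULT2A1 differed by -0.34, SERPINC1 by -0.32, VTN by 0.36, HPX by 0.36, SERPINA3 by 0.35, IGFBP1 by 0.31 and C5 by -0.21.

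Among cell structures, the median was 0.03 over 17 lysosomal genes, -0.02 over 14 autophagy genes, 0.00 over 17 genes of endocytosis and caveolae, 0.06 over 9 genes of EMT and matrix, -0.05 over 21 respiratory chain genes and -0.07 over 27 ribosomal protein genes, all within range. By their means, EMT and matrix lay above it (percentile 99.2) and the respiratory chain list below it (2.22), and ribosomal proteins lay below it with all measured members (1.79) or after quantile normalization (2.43). Apart from NDUFB3, described above, members with large differences included the lysosomal cholesterol transporter NPC1 (0.29), CTSB (-0.21), ATG12 (-0.25), the clathrin light chain CLTB (0.44), RAB7A (-0.20), TIMP1 (0.37), TGFB1 (0.36), COX6C (-0.30), RPL7 (-0.39) and RPLP2 (0.26). The reference transcripts ACTB and GAPDH differed by -0.00 and 0.10. Markers of other cell types were mostly under the level filter: 1 of 10 fibroblast markers, 2 of 11 leukocyte markers (CD68 and LYZ) and 0 of 10 endothelial markers reached it, too few for a list value.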

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

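Both results here come from probes that the comparison did not use, because the annotation supplied no gene name for them. Of 12083 such probes, 3089 reached the level filter, and 20 of these were at least 1.5-fold higher and 98 at least 1.5-fold lower after SiO2-NP. Together these are 3.82% of the 3089, against 0.391% of the expressed named genes, and their differences had an SD of 0.26 against 0.16. The largest positive difference was 1.05 on the log2 scale in probe 7896370 (7.82 in the control and 8.87 after SiO2-NP), and the largest negative one was -2.08 in probe 7896748 (9.20 and 7.12). What these probes measure was not examined, and any control probes of the array among them were not set apart. Their share past the threshold and their SD may therefore not describe transcripts.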

How the results depend on the processing

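Of the 10 lists that stood apart, 8 did so under all 8 alternatives that could move them (centring on the median shifts every gene alike and moves no list's place): cholesterol biosynthesis, fatty acid synthesis, mitosis, DNA replication, core histones, immediate-early and MAPK feedback, hepatocyte transcription factors, and YAP and SRF targets. The NF-kB list fell inside the range with all measured members (percentile 79.6), and the hypoxia and glycolysis list did with all measured members (97.1) or unmatched random lists (97.1). With list means in place of medians, 6 lists lay below the range in place of 3, adding antioxidant enzymes (percentile 2.34), amino acid and urea metabolism (1.12) and the respiratory chain (2.22), and 9 lay above in place of 7, adding p53 targets (99.0) and EMT and matrix (99.2). The iron transport median was 0.0058 with all measured members, against -0.10. Ribosomal proteins lay below the range with all measured members (1.79) or quantile normalization (2.43). With means the hypoxia and glycolysis value was 0.15 in place of 0.06, since a mean gives weight to ALDOC. The counts of genes moved more: without the filter on dim genes they were 61 higher and 68 lower, against 13 and 23, and the filter at the 75th percentile left 8 lower. At 2-fold they were 1 and 4. Higher genes numbered 21 after centring on a running median and 22 after quantile normalization, and lower genes numbered 14 without small and vault RNAs, an alternative chosen after seeing the data, as was a background without zinc finger genes and small RNAs. The cause of the other moves was not tested. Over the 111 named genes and the 4 alternatives run for single genes, the largest move of a difference was 0.15. No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out.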

Other observations

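Gene families were also taken from shared symbol stems with at least 15 expressed genes, after the data had been seen, and some of them (such as RPL and KIF) share members with the lists. Of 64 families, 9 lay below and 8 above the central 95% of matched random lists, against 1.6 per direction by chance. Mitochondrial ribosomal proteins were below the control in 42 of 47 large-subunit (MRPL) genes, with a median of -0.13, and in 21 of 24 small-subunit (MRPS) genes, with a median of -0.12. RNA polymerase (POLR) subunits had a median of -0.10 with 25 of 29 below, and methyltransferase-like (METTL) genes had -0.15 with 18 of 19 below. Such counts alone do not set a family apart. Of the NUP genes 19 of 20 were below, and of the DDX genes 22 of 25, with medians inside their random ranges. Among the families above, the TNF receptor (TNFRSF) genes had a median of 0.14 with 13 of 15 above the control, and the KRTAP genes had 0.19 with 15 of 17 above. The medians of 6 families (MRPL, MRPS, POLR, METTL, TNFRSF and KRTAP) kept their sign after centring on a running median and quantile normalization. Those of the small RNAs and the zinc finger genes did so too. Centring on the median moves every gene alike by 0.0095 and could not change these signs. POLR, the smallest of the 6 medians in size, went from -0.10 to -0.06 under quantile normalization, so a kept sign is a weak check.

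The tests of the patterns below were not all fixed in advance. Those of short-lived transcripts, of array-wide trends, of the number of cultures and of small and vault RNAs were chosen after the results were seen. The lists of further sterol genes, further proliferation genes and LXR targets were not among the 37 fixed lists. They were drawn up for patterns already named by direction, so they were not blind to the results. The higher cholesterol and fatty acid synthesis genes were first set against normalization. Their joint median over 29 expressed genes stayed at 0.53 after centring on a running median by level, above the random range of -0.06 to 0.05. The highest median among the 64 families was 0.19, below that of the lipid genes. The families were not matched to the lipid genes on probe traits such as GC content, so an array-wide trend is not excluded. Further sterol genes outside the lists followed, with a median of 0.30 and 6 of 6 above the control. Their random range was -0.14 to 0.07. They were picked as sterol genes too, so they cannot exclude an effect of the choice of list. Of the listed cholesterol genes under the level filter, PMVK differed by 0.04 and INSIG1 by 0.09. No further fatty acid synthesis genes were examined. Lower cell sterol is a candidate explanation, which predicts lower LXR targets. The median of these targets was -0.11 over 6 expressed genes, with 4 below the control and 2 above. It lay inside the random range of -0.17 to 0.09, which is wide for so few genes, so the test cannot tell either way. A difference between the cultures other than the particles, such as cell density or medium, cannot be told apart with 1 culture per condition.

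The lower proliferation genes had a joint median of -0.17, and after centring on a running median it was -0.14, still below the random range of -0.05 to 0.05, and further mitosis and replication genes outside the lists followed, with a median of -0.14 and 21 of 23 below the control. A loss of short-lived transcripts from the exposed RNA could lower immediate-early genes too, and their median was 0.083. Higher transcription of these genes could mask such a loss, so this explanation is not excluded. An array-wide trend, for example with GC content, stays open: the lowest median among families that are neither small RNAs nor kinesins was -0.15 (METTL), close to the -0.17 of the joint mitosis and replication lists, and no probe sequences were used here. Slower growth of the exposed culture may account for the pattern as well, and with 1 culture per condition it was not tested.

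The vault RNAs were lower beside most small RNAs, whose median of -0.28 over 116 expressed members lay below the random range of -0.06 to -0.00. Lower recovery or labelling of small RNAs in the exposed sample may account for part of this. The 16 expressed genes of the MIR family had a median of 0.12. Symbols that begin with MIR can also name longer host transcripts, so this value cannot decide the question. The vault RNAs were not lower alone, since 99 of the 116 small RNAs were below the control. Of these small RNAs 1.72%, 2 of 116, were lowered at least as much as VTRNA1-3, the least lowered of the 3. Whether the vault RNAs had a further change of their own cannot be told.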
